A study of Homo sapiens with 6 samples.

How the data were processed

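RNA of PC3 cells was measured by RNA sequencing in 6 libraries: 2 untreated, 2 after 2 h and 2 after 4 h of 50 µM heme. Per the labels' protocols, RNA was extracted with Trizol and prepared with an Illumina TruSeq kit. The deposited values are raw read counts per gene symbol, 1 table per library, whose layout and summary lines are those of HTSeq. Per the submitters' processing notes, Trimmomatic, STAR, SAMtools, deepTools and the hg38 build were used; their versions, the annotation release, the strand setting and the read layout are not given in the sources used here. Without the strand setting, reads of overlapping genes and of antisense partners cannot be told apart, so their values are uncertain, as are those of near-identical genes (HSPA1A and HSPA1B, TRIM16 and TRIM16L, histone and ribosomal protein genes).

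The tables held 33514 gene symbols, of which 33164 matched 1 gene of GENCODE release 29 on GRCh38, the source of the coordinates and identifiers. The 5 summary lines stayed out of library sizes and tests. Reads outside annotated genes made up between 5.48% and 6.88% of a library, ambiguous reads between 4.23% and 4.48%, and the count of reads aligned to several places was 0. Gene counts ran from 53129375 to 55537611 per library, mitochondrial messenger RNAs took between 2.33% and 2.73% of them, and the most abundant gene, MT-CO1, at most 0.656%. Depth was thus close to equal between groups. A count of 0 allows up to 3 counts, which is 0.0565 CPM in the shallowest library; such limits cover counting error only. Replicates of a group differed by more than sampling noise (chi-square per gene between 9.89 and 37.8), so none was treated as a duplicate.

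Gene tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr (minimum count 10), which left 16209 genes, and the quasi-likelihood test with all 6 libraries in 1 fit (3 residual degrees of freedom, biological coefficient of variation 0.0982), two-sided, Benjamini-Hochberg adjusted p under 0.05. All groups shared 1 estimate of the spread. The contrasts were 2 h against control, 4 h against control and 4 h against 2 h. Standard errors were derived from the fold change and its F statistic. CPM values of genes use TMM-scaled library sizes; the limits for a count of 0 and the summed CPM of red cell genes use unscaled totals.

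Before the data were examined, 36 gene lists (pathways, complexes, quality and other cell types), the tests and most alternatives were fixed. The 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01), with an estimated correlation beside it, and with fry. Members were counted from the gene test over all genes and after adjustment over the list alone. The genes named were fixed by rule: per contrast, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the libraries of the groups compared; the study genes; and in each list the 4 members with the smallest p. Where a list had 5 or fewer members called in a direction, those outside the rule were named after their values were seen.

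Alternatives were DESeq2 (1.42.0) and its size factors, no filter on low counts, a replicate block, only the compared groups in the fit, glmTreat at 1.5-fold, an estimated correlation and leaving out each library. A per-library correction for GC content and transcript length was added after the data were seen, as were simulations with 4 h set equal to 2 h and a choice of low-abundance genes by the 4 h libraries alone. The gene test was checked on simulated counts of 16209 genes, with a single simulation per time. At 2 h it recovered 67.2% of 67 genes changed 1.5-fold, 97.0% of 67 changed 2-fold and 100% of 66 changed 4-fold. The changed genes all had a control mean of at least 2 CPM, so recovery of scarcer genes was not measured. They were also far fewer than the 5136 genes called in the data at 2 h, so these shares may differ there. Of 16009 unchanged genes 13 were called at 2 h and 10 at 4 h, which made 6.88% and 5.41% of the calls false. Both lay above the nominal 5%, but a single simulation each does not tell this from chance. The planned test of promoter G-quadruplex motifs was not run, since it needs the genome sequence, which was not used here.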

Results

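PC3, a human prostate cancer cell line derived from a bone metastasis, was sequenced without treatment or after 50 µM heme had been in the culture medium for 2 h or 4 h. Heme is the iron-porphyrin group of hemoglobin and of many enzymes. The series concerns hemopexin (a plasma protein that binds heme), heme bound to DNA G-quadruplexes (4-stranded folds of guanine-rich DNA) and MYC. The comparisons ask which genes changed in PC3 cells given heme and whether MYC was among them. There were 3 groups of 2 libraries each. The libraries held between 53129375 and 55537611 reads counted to genes, and 16209 genes were tested. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Fold changes below are log2 values with their standard error (SE) from the fitted model, n = 2 libraries per group. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

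After 2 h, HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 35.8-fold, from 10.9 ± 0.721 to 389 ± 87.5 CPM (counts scaled to library size; SD, n = 2; log2 5.16, SE 0.16, edgeR adjusted p = 3.79e-11). MYC, the transcription factor named in the study's title, rose 2.24-fold, from 519 ± 13.7 to 1163 ± 118 CPM (log2 1.16, SE 0.09, edgeR adjusted p = 1.47e-06). ALAS1, the rate-limiting enzyme of heme synthesis outside red cells, fell 2.01-fold, from 65.2 ± 1.97 to 32.4 ± 4.24 CPM (log2 -1.01, SE 0.12, edgeR adjusted p = 3.97e-05). In the GENCODE annotation of GRCh38, HMOX1 (ENSG00000100292.16) lies on chromosome 22 from 35380361 to 35394214. MYC (ENSG00000136997.17) lies on chromosome 8 from 127735434 to 127741434, and ALAS1 (ENSG00000023330.14) on chromosome 3 from 52198086 to 52214327.

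In all, 5136 of 16209 genes (31.7%) passed the threshold at 2 h, 2579 higher and 2557 lower. A change of at least 2-fold was found for 992 of them, of which 822 were higher. The count was 533 when a change beyond 1.5-fold was required, 2282 without control replicate 1 and 2921 without control replicate 2. On the first principal component of the 6 libraries (58.0% of the variance) the 2 h libraries lay at 55.6 and 39.1, and the control and 4 h libraries between -27.0 and -19.2.

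Among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups, the largest rises at 2 h after HMOX1 were those of C4orf54 (log2 5.01, SE 0.29), the nuclear receptor gene NR4A3 (log2 3.65, SE 0.21), MAML3, a Notch coactivator (log2 2.89, SE 0.26), ADM2 (log2 2.75, SE 0.21), PRR5L (log2 2.74, SE 0.21) and the secreted matrix protein gene CTGF (log2 2.65, SE 0.14). They were followed by ABCG1, a cholesterol exporter (log2 2.62, SE 0.26), FOSB (log2 2.48, SE 0.16) and TENM4 (log2 2.46, SE 0.29). C4orf54 started from 0.245 ± 0.0465 CPM in the controls and NR4A3 from 0.963 ± 0.0797 CPM (SD, n = 2). The largest falls were those of PPARGC1B, a coactivator of mitochondrial gene expression (log2 -2.71, SE 0.15), LRIG3 (log2 -2.22, SE 0.16), the chromatin remodeller CHD7 (log2 -2.11, SE 0.14) and the centromere histone chaperone HJURP (log2 -1.83, SE 0.14). ESM1 (log2 -1.78, SE 0.24), the helicase PIF1 (log2 -1.77, SE 0.20), TBC1D30 (log2 -1.77, SE 0.15), KAZN (log2 -1.76, SE 0.19), the cyclin CCNF (log2 -1.75, SE 0.12) and ANKRD18A (log2 -1.75, SE 0.28) completed the 10 largest falls. The edgeR adjusted p-values of these 20 genes ran from 3.79e-11 for HMOX1 to 4.29e-04 for ANKRD18A. All 138 genes named by rule that passed the threshold at 2 h had both heme libraries on the same side of both controls. The rule required this of these 20 genes and chose most others by a small p, so it is no separate support.

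**Figure D1:**
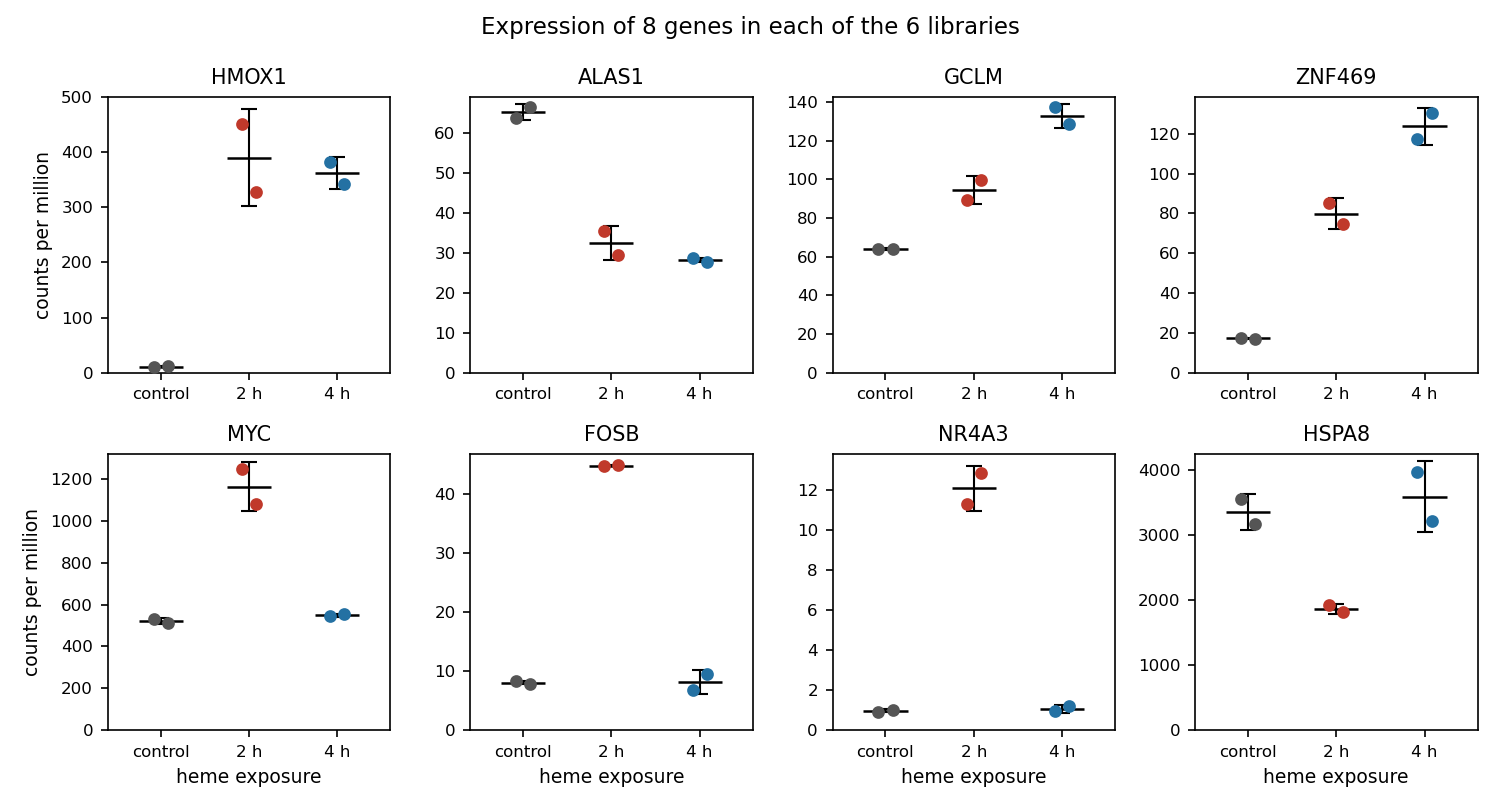
CPM (vertical axes, linear, from 0) of 8 genes in the control, 2 h and 4 h libraries. Each point is a library, the horizontal line is the mean of 2 libraries and the bar is 1 SD; HMOX1, ALAS1, GCLM and ZNF469 differ from the control at both times, while MYC, FOSB, NR4A3 and HSPA8 differ at 2 h and at 4 h do not pass the threshold.

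Of 30 tested immediate early genes, which respond to stimuli without new protein synthesis, 24 rose at 2 h and 0 fell, with the same numbers adjusted over the list alone (median log2 0.63, camera adjusted p = 1.64e-21, adjusted p = 0.181 with an estimated correlation). Among them were NR4A1 (log2 2.42, SE 0.16) and the phosphatase gene DUSP1 (log2 1.41, SE 0.11). Of 30 tested targets of the stress-response factor ATF4, 21 rose, 22 adjusted over the list alone, and 1 fell by either count (camera adjusted p = 3.21e-11, adjusted p = 0.181 with an estimated correlation). TRIB3 (log2 1.75, SE 0.12), the secreted stress factor GDF15 (log2 2.38, SE 0.19) and ATF3 (log2 1.65, SE 0.14) rose, while the member that fell was DDIT3, a pro-apoptotic transcription factor (log2 -0.98). Inflammatory genes known as NF-kB targets moved both ways, with 12 of 23 higher and 5 lower by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.311 with an estimated correlation). The growth factor gene CSF2 (log2 1.75, SE 0.16) and the interleukin gene IL1A (log2 0.90, SE 0.12) rose. The chemokine genes CXCL1 (log2 -0.55), CXCL2 (log2 -0.75), CXCL3 (log2 -0.66) and CCL20 (log2 -0.42) and the NF-kB inhibitor TNFAIP3 (log2 -0.39) fell.

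Known MYC targets of ribosome biogenesis and growth went the other way from MYC itself. Of 57 tested, 40 fell and 0 rose at 2 h, and 44 fell adjusted over the list alone (median log2 -0.41, camera adjusted p = 4.41e-14, adjusted p = 0.0728 with an estimated correlation). The mitochondrial transcription factor TFB2M (log2 -0.85, SE 0.11), the ribosome assembly factors MRTO4 (log2 -0.61, SE 0.09) and UTP20 (log2 -0.75, SE 0.12), and TMEM97 (log2 -0.68, SE 0.10) had the smallest p-values. In the network of MYC and its binding partners, MYC, MXD3 (log2 0.66) and MXD4 (log2 0.45) rose and MGA (log2 -0.68), MAX (log2 -0.39) and MLX (log2 -0.40) fell. That made 3 and 3 of 11 by both counts over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.779). Among 10 tested genes whose promoters are described as forming G-quadruplexes, MYC, PDGFA (log2 0.49) and VEGFA (log2 0.32) rose and HRAS (log2 -0.39) and TERT (log2 -0.93) fell. In this list 4 rose and 3 fell adjusted over the list alone. Camera did not call the list (camera adjusted p = 0.287), while fry called it higher (fry adjusted p = 0.0118). Proteins that bind or unwind G-quadruplexes had 10 of 19 members lower and 0 higher, by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.395 with an estimated correlation). They included the helicases PIF1 and DHX36 (log2 -0.50, SE 0.11) and nucleolin, NCL (log2 -0.58, SE 0.10).

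Of the other genes the study's title or subject names, LRP1, the receptor for heme-hemopexin complexes, rose (log2 0.96, SE 0.15, edgeR adjusted p = 2.86e-04). HPX, the gene of hemopexin, rose from 0.282 ± 0.0989 to 0.771 ± 0.28 CPM (SD, n = 2; log2 1.44, SE 0.46, edgeR adjusted p = 0.0285), on raw counts of 11 and 19 in the controls and 55 and 33 at 2 h. DESeq2 did not call HPX. HP, the haptoglobin gene, had between 5 and 16 counts per library and was not called (log2 0.40, SE 0.64), and CD163, the hemoglobin scavenger receptor gene, had 0 counts in every library. This list held 4 of 5 tested members higher and 0 lower by both counts over all genes and adjusted over the list alone (camera adjusted p = 9.58e-14, adjusted p = 0.181 with an estimated correlation). Its members include HMOX1, at log2 5.16, while its median was 1.16.

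In the list of heme breakdown, ferritin and iron export, HMOX1, the heme transporter SLC48A1 (log2 0.62, SE 0.12) and the ferritin heavy chain FTH1 (log2 0.35) rose. The heme exporter FLVCR1 (log2 -0.78, SE 0.14) and HMOX2 (log2 -0.55, SE 0.11) fell. That is 3 and 2 of 10 by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.00984, adjusted p = 0.396 with an estimated correlation). HMOX1 was at log2 5.16, while the median of this list was 0.041 and its mean 0.50. Of 14 heme synthesis genes, the mitochondrial glycine carrier SLC25A38 (log2 -1.03, SE 0.10), ALAS1, CPOX (log2 -0.48, SE 0.12), ABCB10 (log2 -0.55, SE 0.16) and PGRMC1 (log2 -0.31) fell. ALAD (log2 0.43) and PPOX (log2 0.36) rose, with the same 5 and 2 adjusted over the list alone (camera adjusted p = 0.0336, adjusted p = 0.311 with an estimated correlation). Among 9 iron uptake genes LRP1 rose and the transferrin receptor TFRC (log2 -0.39, SE 0.11) and IREB2 (log2 -0.34, SE 0.12) fell, the same adjusted over the list alone. Iron uptake was not called (camera adjusted p = 0.893). NRF2 targets, which serve antioxidant defence, had 9 of 32 members higher and 2 lower by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.395 with an estimated correlation). TRIM16L (log2 1.16, SE 0.13), the cystine transporter SLC7A11 (log2 1.16, SE 0.14) and GCLM (log2 0.56, SE 0.10) rose, and TXN (log2 -0.52) and PRDX1 (log2 -0.46) fell. Of 4 tested metallothionein-list genes, SLC30A1 (log2 -0.74, SE 0.13), MT1X (log2 -0.52, SE 0.12) and MT2A (log2 -0.33, SE 0.09) fell and 0 rose, the same adjusted over the list alone.

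Of 24 heat shock genes at 2 h, 13 fell and 1, DNAJB4 (log2 0.41), rose, and adjusted over the list alone 14 fell and 2 rose (camera adjusted p = 8.02e-05, adjusted p = 0.395 with an estimated correlation). HSPA8, the constitutive HSP70 (log2 -0.85, SE 0.10), HSPH1 (log2 -0.86, SE 0.12) and the mitochondrial chaperonin HSPE1 (log2 -0.74, SE 0.11) were among those lower. Of 17 endoplasmic reticulum chaperone genes, 9 fell, such as HSP90B1 (log2 -0.48, SE 0.10) and CRELD2 (log2 -0.57, SE 0.11), and DNAJB9 (log2 0.42) rose, the same adjusted over the list alone (camera adjusted p = 0.00258, adjusted p = 0.311 with an estimated correlation). Proteasome subunits had 16 of 33 members lower and 0 higher, and 19 lower adjusted over the list alone (camera adjusted p = 1.38e-05, adjusted p = 0.396 with an estimated correlation). PSMD12 had the smallest p of them (log2 -0.63, SE 0.11). Cytosolic ribosomal proteins had 11 of 77 lower and 0 higher, and 0 in either direction adjusted over the list alone (median log2 -0.21, camera adjusted p = 8.56e-05, adjusted p = 0.69 with an estimated correlation). Nuclear-encoded subunits of oxidative phosphorylation had 21 of 73 lower, such as NDUFB3 (log2 -0.64, SE 0.12). COX6B2 (log2 0.93, SE 0.16) and UQCRHL (log2 0.95) were higher, and the counts were the same adjusted over the list alone (camera adjusted p = 3.6e-04, adjusted p = 0.566 with an estimated correlation).

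Of 30 DNA replication genes at 2 h 15 fell and 0 rose by both counts over all genes and adjusted over the list alone (camera adjusted p = 9.88e-07, adjusted p = 0.496 with an estimated correlation). Among them were the cyclin CCNE1 (log2 -1.05, SE 0.14), GINS3 (log2 -0.92, SE 0.13) and RRM2, a ribonucleotide reductase subunit (log2 -0.92, SE 0.13). Of 26 mitotic genes 15 fell, among them the kinase AURKA (log2 -0.81, SE 0.09) and the cyclin CCNA2 (log2 -0.86, SE 0.13). The phosphatase CDC25C rose (log2 0.87, SE 0.14), and the counts were the same adjusted over the list alone (camera adjusted p = 1.81e-05, adjusted p = 0.311 with an estimated correlation). Of 22 cholesterol genes 7 fell, such as SQLE (log2 -0.57, SE 0.10), the same adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.311 with an estimated correlation). YAP targets had 6 of 16 higher, led by CTGF and CYR61 (log2 0.58, SE 0.09). F3 (log2 -0.55, SE 0.10) and AMOTL1 (log2 -0.41) were lower, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.313 with an estimated correlation). Autophagy and lysosome genes had 8 of 23 higher, with the autophagy kinase ULK1 (log2 1.80, SE 0.13) and SQSTM1 (log2 0.56, SE 0.10). ATG12 (log2 -0.51), ATG5 (log2 -0.44) and ATG16L1 (log2 -0.28) were lower, the same adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.552 with an estimated correlation).

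**Figure D2:**
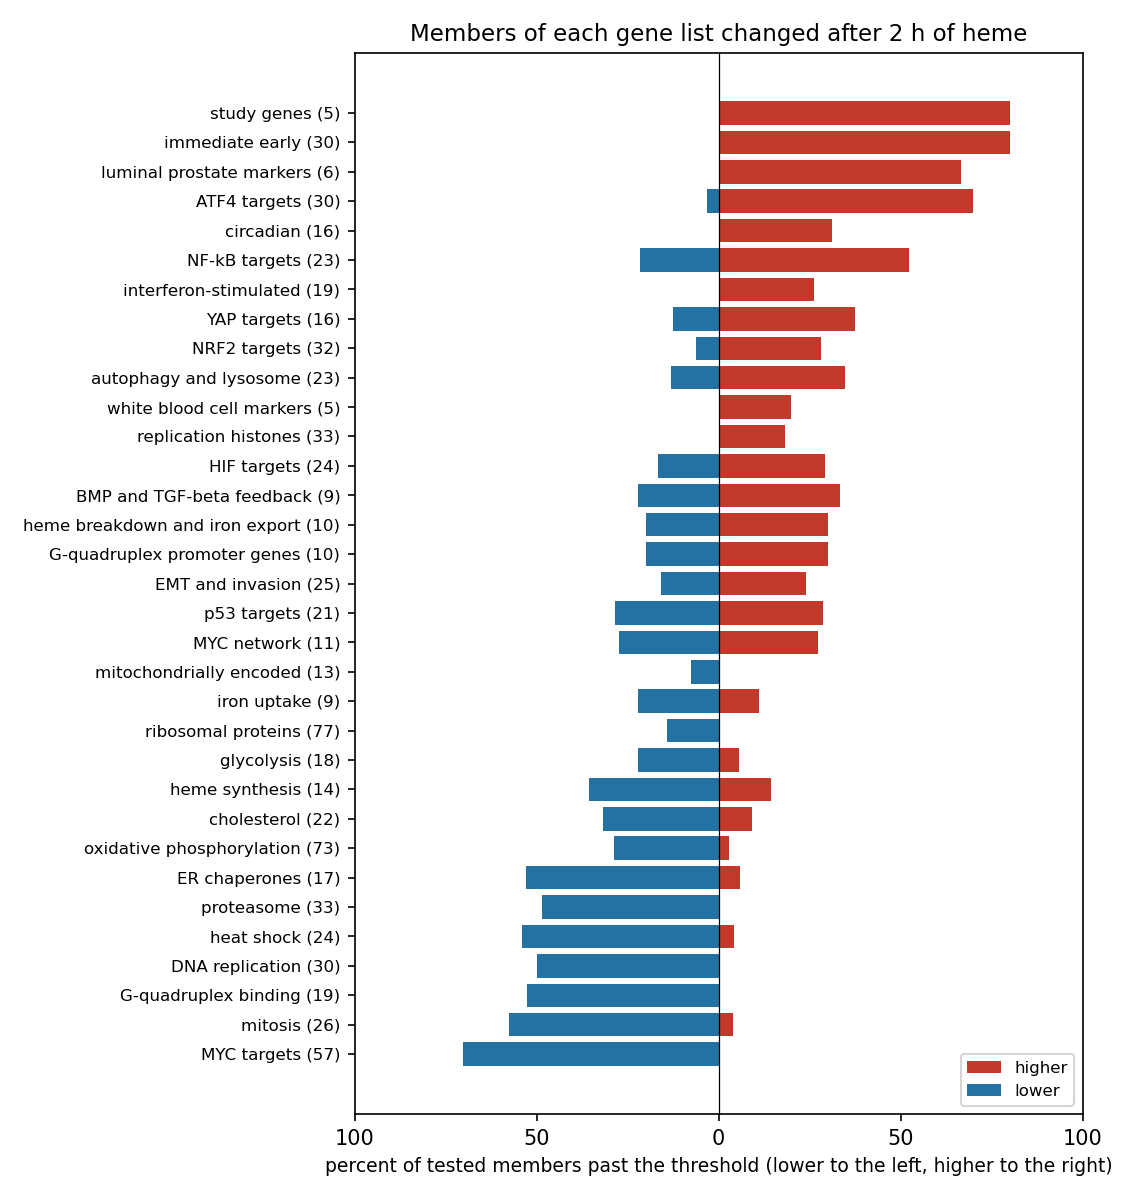
Percent of the tested members of each gene list (number tested in parentheses) that passed the threshold after 2 h of heme, higher to the right and lower to the left of 0. Immediate early genes have 24 of 30 members higher and MYC targets 40 of 57 lower.

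Camera called none of the remaining lists at 2 h, apart from the luminal prostate markers. Clock genes had 5 of 16 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.108): ARNTL (log2 1.03, SE 0.17), DBP (log2 1.29, SE 0.30), BHLHE41 (log2 0.43), PER3 (log2 0.43) and NPAS2 (log2 0.37). Interferon-stimulated genes had 5 of 19 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0502): STAT2 (log2 0.75), IRF1 (log2 0.75), IFIT1 (log2 0.99), IRF7 (log2 0.51) and MX1 (log2 0.52). p53 targets split into 6 higher, with PLK3 (log2 0.82, SE 0.12), and 6 lower, with TIGAR (log2 -0.75, SE 0.12), of 21 by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.861). HIF targets had 7 of 24 higher, led by ANGPTL4 (log2 1.56, SE 0.20). PDK1 (log2 -0.58), LDHA (log2 -0.41), EGLN1 (log2 -0.47) and PGK1 (log2 -0.26) were lower, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.8). Of 18 glycolysis genes ENO2 rose (log2 0.71) and HK2 (log2 -0.55), LDHA, TPI1 (log2 -0.26) and PGK1 fell, the same adjusted over the list alone (camera adjusted p = 0.356). Genes of epithelial-mesenchymal state and invasion had 6 of 25 higher, such as MMP9 (log2 1.03, SE 0.20). ZEB1 (log2 -1.26, SE 0.26), TGFBI (log2 -0.46), MMP3 (log2 -0.81) and TWIST1 (log2 -0.60) were lower, with 11 and 5 adjusted over the list alone (camera adjusted p = 0.345). Of 9 BMP and TGF-beta feedback genes SMAD6 (log2 1.54, SE 0.24), ID2 (log2 0.61) and BAMBI (log2 0.62) rose and PMEPA1 (log2 -0.32) and ID1 (log2 -0.42) fell. The counts were 3 and 3 adjusted over the list alone (camera adjusted p = 0.779).

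Markers of other cell types and of RNA quality were tested in the same way at 2 h. The luminal prostate markers HOXB13 (log2 0.80, SE 0.15), STEAP2 (log2 0.52, SE 0.12), SLC45A3 (log2 0.43, SE 0.12) and TMPRSS2 (log2 1.22, SE 0.37) rose. That is 4 of 6 and 0 lower by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.0333, adjusted p = 0.311 with an estimated correlation). KLK3 and FOLH1 of that list had 0 counts in every library, which allows up to 0.0565 CPM in the shallowest. CD14, a monocyte marker, rose from 0.601 ± 0.277 to 2.21 ± 0.494 CPM (SD, n = 2) as the 1 of 5 blood cell markers called, by both counts over all genes and adjusted over the list alone (camera adjusted p = 0.503). The collagen gene COL1A1 rose (log2 0.70, SE 0.14) as 1 of 2 tested fibroblast markers. Red cell genes summed to at most 0.344 CPM in any library and none was tested. Of 13 messenger RNAs encoded in mitochondria MT-CO2 fell (log2 -0.25, SE 0.09), and 0 were called adjusted over the list alone (camera adjusted p = 0.161). Replication-dependent histone genes had 6 of 33 higher, such as HIST2H2BE (log2 0.91, SE 0.19), and 5 adjusted over the list alone (camera adjusted p = 0.0909). With camera's preset correlation 20 of 33 lists were called at 2 h, 9 up and 11 down, and 0 with an estimated correlation. Without the filter on low counts the calls of heme breakdown and iron export (camera adjusted p = 0.755), autophagy (camera adjusted p = 0.0936) and YAP targets (camera adjusted p = 0.107) were lost, the last also with a GC and length correction. Leaving out a single library ended the calls of the heme synthesis, NF-kB, cholesterol, YAP, autophagy, ribosomal protein and luminal lists. Calls were also gained. Interferon-stimulated genes were called higher with DESeq2's size factors (camera adjusted p = 0.0489), without the filter on low counts (camera adjusted p = 0.0165), with the GC and length correction (camera adjusted p = 0.0386) and without control replicate 1 (camera adjusted p = 0.0321). Without the filter, clock genes were called higher (camera adjusted p = 0.0407) and mitochondrially encoded messenger RNAs lower (camera adjusted p = 0.0296), and histone genes were called higher without 2 h replicate 2 (camera adjusted p = 0.0404). Fry, which asks whether a list's own genes move one way on balance, called 16. The median, mean and camera test of a list differed in sign at 2 h for the iron uptake, MYC network, HIF target, G-quadruplex promoter and BMP lists, none of which camera called.

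At 4 h, 5 genes passed the threshold, and HMOX1 was still 33.2-fold above the control at 362 ± 28.8 CPM (SD, n = 2; log2 5.05, SE 0.15, edgeR adjusted p = 4.84e-11). ZNF469, a zinc finger gene linked to corneal collagen, rose 7.18-fold from 17.2 ± 0.193 to 124 ± 9.22 CPM (log2 2.84, SE 0.12, edgeR adjusted p = 1.55e-09). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 2.08-fold (log2 1.05, SE 0.10, edgeR adjusted p = 1.6e-04), and CYP1B1, a cytochrome P450 enzyme, rose 1.59-fold (log2 0.66, SE 0.10, edgeR adjusted p = 0.0378). ALAS1 fell 2.31-fold to 28.2 ± 0.553 CPM (log2 -1.21, SE 0.12, edgeR adjusted p = 1.88e-04). ZNF469 (ENSG00000225614.2) lies on chromosome 16 from 88427471 to 88440757. GCLM (ENSG00000023909.9) lies on chromosome 1 from 93885205 to 93909456 and CYP1B1 (ENSG00000138061.11) on chromosome 2 from 38066973 to 38109902.

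MYC at 4 h was at 548 ± 6.73 CPM and did not pass the threshold (log2 0.08, SE 0.09, edgeR adjusted p = 1.0), nor did LRP1 (log2 0.23, SE 0.15) or HPX (log2 0.18, SE 0.51). At 4 h 583 of the 16209 genes had an unadjusted edgeR p under 0.05. Chance alone would give 810, so the test was conservative here and may have missed changed genes. DESeq2 called 15 genes, as did a fit of only the control and 4 h libraries. All groups shared 1 spread, and the 2 h replicates differed most (chi-square per gene 37.8, against 9.89 in the controls and 25.2 at 4 h). The call of CYP1B1 was lost when either control or either 4 h library was left out, and that of ALAS1 without 4 h replicate 2, which left 3 genes.

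NRF2 targets at 4 h had 1 of 32 members higher over all genes, GCLM, and 3 adjusted over the list alone (median log2 0.15, camera adjusted p = 9.54e-11, adjusted p = 0.178 with an estimated correlation). The other 2 were TRIM16 at log2 0.45 and TXNRD1 at log2 0.31, while NQO1 was at log2 0.27. The cholesterol list was called higher with 0 of 22 members past the threshold by either count over all genes and adjusted over the list alone (median log2 0.16, camera adjusted p = 1.44e-06, adjusted p = 0.129 with an estimated correlation). SQLE was at log2 0.28. Heat shock genes (median log2 0.14, camera adjusted p = 1.5e-05, adjusted p = 0.461 with an estimated correlation) and endoplasmic reticulum chaperones (median log2 0.10, camera adjusted p = 4.77e-04, adjusted p = 0.276 with an estimated correlation) were called higher, and had been called lower at 2 h. Clock genes were also called higher (camera adjusted p = 0.0195, adjusted p = 0.276 with an estimated correlation). None of these 3 lists had a member past the threshold over all genes or adjusted over the list alone. The study genes (camera adjusted p = 1.97e-40, adjusted p = 0.12 with an estimated correlation) and the heme breakdown and iron export list (camera adjusted p = 4.68e-23, adjusted p = 0.129 with an estimated correlation) held HMOX1 as the 1 member called by both counts over all genes and adjusted over the list alone. HMOX1 was at log2 5.05, while the medians of these lists were 0.18 and 0.058.

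Lists called lower at 4 h were heme synthesis, with ALAS1 as its 1 called member over all genes and adjusted over the list alone (camera adjusted p = 0.0195, adjusted p = 0.276 with an estimated correlation), and 8 lists with 0 members past the threshold over all genes. BMP and TGF-beta feedback genes had 3 of 9 lower adjusted over the list alone (median log2 -0.28, camera adjusted p = 4.19e-05, adjusted p = 0.218 with an estimated correlation). Values were ID1 at log2 -0.47, ID3 at log2 -0.46 and PMEPA1 at log2 -0.36. HIF targets had 2 of 24 lower adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.561 with an estimated correlation). Their values were KDM3A at log2 -0.57 and PDK1 at log2 -0.44. NF-kB targets had 1 of 23 lower adjusted over the list alone (camera adjusted p = 4.07e-05, adjusted p = 0.178 with an estimated correlation), with NFKBIZ at log2 -0.44. Mitotic genes (median log2 -0.15, camera adjusted p = 3.36e-06, adjusted p = 0.276 with an estimated correlation) and oxidative phosphorylation (camera adjusted p = 1.76e-07, adjusted p = 0.578 with an estimated correlation) had 0 members called adjusted over the list alone. Mitochondrially encoded messenger RNAs (camera adjusted p = 3.09e-06, adjusted p = 0.527 with an estimated correlation), the proteasome (camera adjusted p = 0.00617, adjusted p = 0.667 with an estimated correlation) and glycolysis (camera adjusted p = 0.045, adjusted p = 0.632 with an estimated correlation) also had 0 members called adjusted over the list alone. Of 4 tested metallothionein-list genes 0 passed over all genes and 4 were lower adjusted over the list alone: MT1F at log2 -0.38, MT1X at log2 -0.36, SLC30A1 at log2 -0.32 and MT2A at log2 -0.26. Of the invasion genes TGFBI was lower adjusted over the list alone (log2 -0.47). MYC targets were not called at 4 h, with 0 of 57 members past the threshold by either count over all genes and adjusted over the list alone (camera adjusted p = 0.522). Immediate early genes (camera adjusted p = 0.528) and ATF4 targets (camera adjusted p = 0.171) likewise had 0 members past the threshold over all genes and adjusted over the list alone. The 4 h call of heme synthesis was lost without the filter on low counts (camera adjusted p = 0.315) and that of the proteasome with the GC and length correction (camera adjusted p = 0.0673). That of glycolysis was lost with DESeq2's size factors (camera adjusted p = 0.0682) and with a replicate block (camera adjusted p = 0.0616). Leaving out a single library ended these 3 calls and those of the heat shock, chaperone, clock, HIF target, oxidative phosphorylation and mitochondrially encoded lists. Ribosomal proteins, not called at 4 h with all libraries and no replicate block (camera adjusted p = 0.0922), were called lower with the block (camera adjusted p = 0.0432). They were also called lower without 4 h replicate 1 (median log2 -0.18) or control replicate 2 (median log2 -0.075), and higher without 4 h replicate 2 (median log2 0.084). Immediate early genes were called lower without control replicate 1 (camera adjusted p = 0.0427). Of 33 lists 16 were called at 4 h, 7 up and 9 down, and 0 with an estimated correlation. Fry called 1, heme synthesis (fry adjusted p = 0.026). The median, mean and test differed in sign at 4 h for immediate early genes, interferon, autophagy, G-quadruplex promoter and histone lists, none of them called.

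All 5 genes called at 4 h had been called in the same direction at 2 h. Independent lists of these sizes would share 0.636 higher and 0.158 lower genes, and 50 simulations of unchanged groups against the same controls shared 0. Those simulations held no changed genes, while 5136 were called at 2 h, so their 0 does not measure sharing by chance here. The controls could not be split with 2 libraries on each side, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, the log2 fold changes at both times had a covariance of 0.060 and a simulated covariance of 0.0456, and a correlation of 0.300 against a simulated 0.506. The simulated values are those that shared controls give when no gene changes, which was not the case at 2 h.

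**Figure D3:**
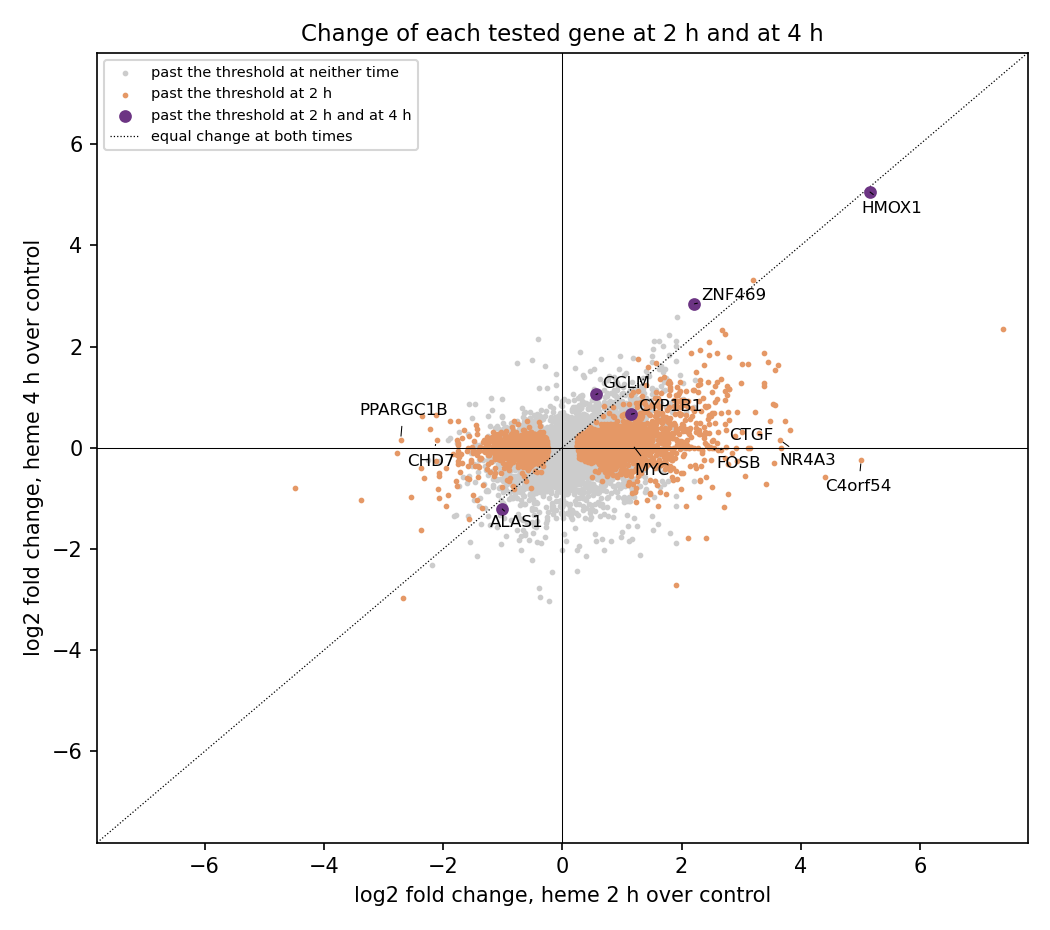
Each point is 1 of the 16209 tested genes, with its log2 fold change over the control at 2 h (horizontal) and at 4 h (vertical), coloured by the times at which it passed the adjusted p threshold of 0.05. HMOX1, ZNF469, GCLM, CYP1B1 and ALAS1 passed at both times, and MYC, NR4A3 and FOSB lie near 0 on the vertical axis.

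The difference between the times was tested directly. From 2 h to 4 h MYC fell 2.12-fold (log2 -1.08, SE 0.09, edgeR adjusted p = 2.28e-06) and LRP1 fell 1.66-fold (log2 -0.73, SE 0.15, edgeR adjusted p = 0.00197). HMOX1 (log2 -0.11, SE 0.13, edgeR adjusted p = 0.566) and ALAS1 (log2 -0.20, edgeR adjusted p = 0.222) did not differ between the times by this test, and HPX missed the threshold (log2 -1.26, SE 0.46, edgeR adjusted p = 0.0521). ZNF469 (log2 0.63, edgeR adjusted p = 6.07e-04) and GCLM (log2 0.49, edgeR adjusted p = 0.0022) rose further, and CYP1B1 fell (log2 -0.49, edgeR adjusted p = 0.00267).

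In total 4558 genes differed between the times, 2270 higher and 2288 lower at 4 h. Of the 2579 genes higher at 2 h, 1848 were then lower at 4 h than at 2 h, and of the 2557 lower at 2 h, 1962 were then higher, together 74.2% of the 2 h calls. The 2 h libraries are part of both comparisons, so some reversal of sign comes from them. In 50 simulations with 4 h set equal to 2 h, at most 2 genes were called in opposite directions, against 3810 observed. Shared libraries alone thus gave almost no such calls where no gene differed between the times. How much they add where many genes differ was not measured. Without regard to the second call, 99.7% of the 2 h calls had the opposite sign from 2 h to 4 h, against a simulated 59.5%. By the same rule, the largest falls from 2 h to 4 h were those of C4orf54 (log2 -5.25, SE 0.30), NR4A3 (log2 -3.49, SE 0.21), PRR5L (log2 -2.73, SE 0.21), CTGF (log2 -2.69, SE 0.14), ABCG1 (log2 -2.66, SE 0.27), MAML3 (log2 -2.65, SE 0.25), SLITRK6 (log2 -2.58, SE 0.21), FOSB (log2 -2.46, SE 0.16), NEDD9 (log2 -2.40, SE 0.19) and ADM2 (log2 -2.40, SE 0.20). The largest rises were those of PPARGC1B (log2 2.86, SE 0.15), LRIG3 (log2 2.59, SE 0.17), KAZN (log2 2.29, SE 0.19), CHD7 (log2 2.25, SE 0.15), TBC1D30 (log2 1.91, SE 0.15), RAB3A (log2 1.89, SE 0.15), KIAA1586 (log2 1.83, SE 0.25), ZNF165 (log2 1.81, SE 0.19), GUCY1A1 (log2 1.80, SE 0.21) and CCNF (log2 1.80, SE 0.12). The count was 543 when a difference beyond 1.5-fold was required and 2181 without 4 h replicate 1.

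Immediate early genes had 22 of 30 members lower at 4 h than at 2 h and 0 higher, 26 lower adjusted over the list alone (camera adjusted p = 1.03e-23, adjusted p = 0.188 with an estimated correlation). MYC targets had 39 of 57 higher and 0 lower, 47 higher adjusted over the list alone (camera adjusted p = 7.42e-16, adjusted p = 0.0609 with an estimated correlation), such as MYBBP1A (log2 0.76, SE 0.09). ATF4 targets had 19 of 30 lower, with ATF3 (log2 -1.95, SE 0.14). The 1 higher was DDIT3 (log2 0.98), with 21 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.23e-10, adjusted p = 0.188 with an estimated correlation). Heat shock genes had 15 of 24 higher, with HSPH1 (log2 1.13, SE 0.12). DNAJB2 (log2 -0.38) was lower, with 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.27e-08, adjusted p = 0.395 with an estimated correlation). Of 33 lists 15 differed between the times, 9 up and 6 down, 0 with an estimated correlation and 13 by fry. Lists that camera called and fry did not were the study genes, DNA replication, mitosis, proteasome, autophagy, ribosomal proteins and G-quadruplex binding. Signs of median, mean and camera test differed here for the heme breakdown, iron uptake, MYC network, glycolysis and G-quadruplex promoter lists, none of them called by camera. Fry called the G-quadruplex promoter list lower (fry adjusted p = 0.0135).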

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

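The tests of exchanged libraries, of a rise of MYC targets above the control by 4 h, of reads outside annotated genes and of genes chosen by the 4 h libraries were added after the results were seen. A test of the difference between the times drew attention to 4558 genes and 15 gene lists whose level at 4 h differed from that at 2 h, and to 164 of the 269 genes named by rule. The list calls were made with camera's preset correlation of 0.01. With an estimated correlation 0 lists were called, while fry called 13 between the times. For MYC targets the estimate was -0.0052, below the preset, so a higher correlation between genes does not explain the loss of that call. The cholesterol and luminal prostate lists, with estimates of -0.017 and -0.17, lost their calls too. An estimated correlation thus ended calls for a reason other than a high correlation, and that reason was not tested. MYC differed by a log2 value of -1.08, LRP1 by -0.73, CYP1B1 by -0.49, GCLM by 0.49 and ZNF469 by 0.63.

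At 2 h 5136 genes passed the threshold and at 4 h 5, a contrast that the conservative test at 4 h may overstate. A bias from GC content and transcript length is not enough to account for it: 90.2% of the 2 h calls kept their direction and their call after a correction for both, although the 10% of genes with the lowest GC content had a median log2 of -0.21 at 2 h and the 10% with the highest 0.26. The trend was larger in 2 h replicate 1: without it the medians were -0.068 and 0.16, and without 2 h replicate 2 they were -0.37 and 0.34. Depth is not enough either, since 98.7% of the 2 h calls remained after thinning to the smallest library, where the totals had differed little to begin with. Untreated libraries in the place of the 4 h ones are excluded by HMOX1, 33.2-fold above the control at 4 h. A transient response to heme and a difference in handling between the 2 h dishes and the others, such as a medium change, were not told apart by any test here and stay open.

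MYC was higher and its known targets lower at 2 h. After the GC and length correction the median of the targets was -0.48 on the log2 scale and the list was still called lower with camera's preset correlation, so that bias does not account for it. Without the GC and length correction, the camera call of the list was lost when the correlation was estimated (adjusted p = 0.0728 with an estimated correlation). The estimate was -0.0048, below the preset 0.01, so a higher correlation between the targets does not explain that loss, whose cause was not tested. Fry called the list lower (fry adjusted p = 0.0015). From 2 h to 4 h 39 of 57 targets rose and 0 fell (edgeR's quasi-likelihood test). A delayed rise above the control was not seen by 4 h, where their median over it was 0.0060, with a bootstrap interval over genes from -0.013 to 0.031; a later rise stays open. Genes as abundant as the targets did not fall alike: the list's median lay at percentile 0 of 10000 lists matched on mean expression, whose own 5th percentile was -0.17.

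Genes of low abundance had fold changes at 2 h that leaned upward, with a median log2 of 0.41 in the 10% with the lowest expression (interquartile range -0.21 to 1.06). Few passed the threshold, 145 of 1621 higher and 19 lower. The median was 0.38 after the GC and length correction, and the lower of its values without either 2 h replicate was 0.39, but neither decides, because the 2 h libraries help choose these genes. The 4 h libraries are not part of the 2 h comparison, and the 10% chosen and filtered by them alone (1500 genes) had a median of 0.35 (bootstrap interval over genes 0.30 to 0.41), with 187 higher and 22 lower. So the choice of genes is not enough to account for it. In these genes the median was 0.33 after the correction and at least 0.34 without either 2 h replicate, which argues against that bias and against a single library. Reads from genomic DNA or unspliced RNA cannot be told apart from it: the lower 2 h library held a share of reads outside annotated genes that differed by -0.401 percentage points from the lower control, but the other 2 h library, at 6.88%, exceeded both controls. The bound written for this test was met by the first library; after the values were seen, 1 library was judged too few to exclude the explanation.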

How the results depend on the processing

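The GC and length correction was chosen after the data were seen. The direction and call of MYC and HMOX1 at both times held in every alternative run for them, with MYC between 1.06 and 1.26 at 2 h and between 0.053 and 0.11 at 4 h when 1 library was left out, and HMOX1 between 4.91 and 5.37 and between 4.97 and 5.13 (log2). Leaving out a library leaves its group with 1, which is then assumed to vary like the others. The count at 2 h became 533 with glmTreat and ran from 2282 (without control replicate 1; 2921 without control replicate 2) to 6195 without 2 h replicate 2; with the GC and length correction it was 6431, of which 2801 were higher and 3630 lower. That at 4 h became 10 without a filter, 15 with DESeq2, with only the compared groups and with the GC and length correction, and 3 with glmTreat, and ran from 3 without 4 h replicate 2 to 15 without either 2 h replicate. Genes called at both times numbered 8 without a filter, 11 with DESeq2 and with the correction, 3 with glmTreat, and from 3 without 4 h replicate 2 to 11 without 2 h replicate 2 (10 without 2 h replicate 1). The difference between the times gave 543 genes with glmTreat, and from 2181 without 4 h replicate 1 to 5720 without 2 h replicate 2, and with the GC and length correction 6318, 3575 higher and 2743 lower. With an estimated correlation 0 lists were called at 2 h, 0 at 4 h and 0 between the times; leaving out a library gave 14 to 21, 11 to 15 and 13 to 14. Except for glmTreat, which asks for a larger change, the cause was not tested. Replicate numbers did not pair the libraries (correlations of deviations -0.091, 0.065 and -0.016), and a replicate block gave 4809, 6 and 4205 genes. No named gene reversed. With the GC and length correction, 414 of the named results were unchanged in call, 10 gained it and 7 lost it. With glmTreat 194 lost it, and leaving out a library lost from 7 (2 h replicate 2) to 47 (control replicate 1); DESeq2 did not call HPX at 2 h. The planned promoter G-quadruplex tests were not run. Depth limits HPX and HP, with under 60 counts per library.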

Other observations

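The symbol prefixes and gene types in this paragraph and the next were chosen after the results were seen. Among 66 prefixes of protein-coding symbols (the letters before the first digit), 14 had more or fewer calls at 2 h than other protein-coding genes. Not all are described here, which leaves out an excess of higher calls. A prefix need not be a gene family: AC (3 of 69 lower) and SH (0 of 32 lower) were among the 14. The test was Fisher's exact test, two-sided, Benjamini-Hochberg adjusted within prefixes, and within gene types below. Genes are not independent replicates. Zinc finger genes named ZNF had 114 of 415 members lower (27.5% against 18.1% of protein-coding genes, odds ratio 1.74, adjusted p = 1.33e-04) and 27 higher (6.51% against 16.6%, odds ratio 0.343, adjusted p = 9.38e-08). Large-subunit mitochondrial ribosomal proteins (MRPL) had 23 of 49 lower (odds ratio 4.02, adjusted p = 1.57e-04), RNA-binding motif genes (RBM) 18 of 35 (odds ratio 4.80, adjusted p = 2.71e-04), DEAD-box helicases (DDX) 16 of 34 (odds ratio 4.03, adjusted p = 0.00276), RNA polymerase subunits (POLR) 13 of 29 (odds ratio 3.68, adjusted p = 0.0137) and translation initiation factors (EIF) 20 of 54 (odds ratio 2.67, adjusted p = 0.0154). Their median log2 at 2 h ran from -0.31 for RBM to -0.15 for EIF.

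Of 28 collagen genes (COL) 0 were lower (Fisher's exact test, adjusted p = 0.0447), against 18.1% of protein-coding genes, with a median log2 of 0.32 that became 0.035 after the GC and length correction. Genes of solute carriers (SLC) had 26 of 253 lower (odds ratio 0.512, adjusted p = 0.0130) and 53 higher (adjusted p = 0.236), and 0 of 34 histone genes (HIST) were lower (adjusted p = 0.0282). Long intergenic RNAs had a median log2 of 0.28 at 2 h and antisense RNAs 0.20, and 30 of 1006 and 33 of 1374 were lower (Fisher's exact test, adjusted p = 2.56e-41 and 7.00e-64 against all other annotated genes), while at 4 h their medians were -0.010 and -0.025. Calls in the other direction were not in excess: 142 long intergenic RNAs were higher (14.1% against 16.0% of annotated genes, Fisher's exact test, adjusted p = 0.10), and 160 antisense RNAs (11.6%, odds ratio 0.674, adjusted p = 3.02e-06). Since the strand setting is not stated, antisense values may hold reads of the opposite gene, and low abundance goes with an upward lean, with a median of 0.35 in the 10% of genes lowest by the 4 h libraries. Genes of low abundance were also seldom called. In the 10% with the lowest expression 145 of 1621 were higher and 19 lower, while 31.7% of all tested genes were called. The Fisher tests did not match on abundance, so scarce calls in a prefix or gene type may reflect low counts.

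CYP1B1 was called at 4 h, and TIPARP (log2 0.45) by DESeq2. Both are known targets of the aryl hydrocarbon receptor, so a hypothesis was that other targets rose together. A list of 9 others was written before their values were looked up, 7 of which were tested. Their median log2 at 4 h was 0.15, below the 0.2 set in advance, with 6 of 7 above 0 and 0 called. A bootstrap interval from 0.082 to 0.23, added after the value was seen, includes 0.2, so the test does not decide.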
